A study of Mus musculus with 2 samples.

How the data were processed

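MicroRNA sequencing was carried out on total RNA of stomach tissue from mouse embryos of strain B6NCrl at 14.5 days of development, size selected below 30 nt. The labels describe 2 biological replicates of the same group, each from a stomach of an embryo collected on its own day. They also give the sex of each sample as both male and female, so a pool of embryos is not excluded, and sex was not used here. No treatment, genotype, age or tissue varied between the samples, and no comparison between conditions could be made. The collection day and the replicate are the same split, so a difference between the libraries cannot be assigned to either.

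The deposited unit is counts per gene, as whole numbers, in 1 table per library. Per the file text that accompanies the tables, they were made on the mm10 assembly with the GENCODE M4 annotation and derived from an alignment. The aligner and the counting program are not given in the sources used here. The tables have no header. They hold 3 count columns, and from the values the deposited counts of the 2nd and 3rd columns, which separate the strands, add up to those of the 1st for every gene. The 1st column, which counts both strands, was used throughout, by a rule fixed in advance for files that do not name their columns. Without strand, reads from a gene and from an antisense partner cannot be told apart, and the separate columns are used in the closing part for that purpose. Before any gene, each table gives 4 lines that name no gene. They held unmapped reads, 13.0% ± 0.72 of all reads (SD, n = 2), reads that map to several places, 27.6% ± 0.28, reads outside the annotated genes, 2.41% ± 0.13, and ambiguous reads, 0 in both libraries. These lines were left out of the totals and tests. Reads that map to several places were thus not counted for any gene, and genes whose mature sequence occurs at several loci can be undercounted by an amount the tables do not give.

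The 1973 genes of the tables were given symbols and coordinates from GENCODE M21 on the same assembly (GRCm38, mm10) by their Ensembl identifier without its version. A symbol was found for 1894 of them, all annotated as miRNA genes, and the other 79 held 4 counts in all. GENCODE M21 has 308 further miRNA genes that are not among the genes counted here, out of 2202. Host genes are those of the same strand in GENCODE M21. A gene is described as sharing sequence when its precursor has 20 nt or more in common with another miRNA precursor of GENCODE M21 at another locus. Its level is uncertain for that reason.

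The total over genes was 5004548 counts in replicate 1 and 4679914 in replicate 2. Levels are counts per 1000000 gene counts (CPM), given as mean ± SD of the 2 libraries. A count of 3, the upper limit that a count of 0 allows, is 0.599 CPM in replicate 1 and 0.641 CPM in replicate 2. Reads carry no molecular identifiers, so floors and intervals cover counting error only. CPM values are shares of the counted miRNA and not amounts per cell. A gene was called detected with 10 or more counts in both libraries.

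Agreement between the libraries was described by Pearson's r and Spearman's rho of log2(CPM + 1) across detected genes, which are not independent replicates. Differences between the libraries were tested gene by gene with an exact conditional binomial test, two-sided, on the deposited counts, with Benjamini-Hochberg adjustment over the detected genes, an adjusted p under 0.05 and an absolute log2 ratio of 1 or more. The ratio is replicate 2 over replicate 1. This test compares these libraries and not conditions. A chi-square over the detected genes asked whether the libraries differed by more than sampling noise. With 1 group of 2 samples, a quasi-likelihood test has no contrast to fit. For each list with 3 or more detected members, 18 of the 24 lists, the median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 10 bins. The random lists do not keep genes of 1 locus together, as a cluster list does. The percentile describes these libraries and is not a p-value. Log2 ratios between list totals were taken within each library and carry no test, since 2 libraries cannot pass a threshold in an exact test. The SD of a ratio between different miRNAs covers the spread between libraries and no error that both libraries share.

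The miRNA lists, the pairs of neighbouring precursors, the tests, the thresholds and most alternatives were fixed before the data were examined. The genes named are the 20 with the highest mean CPM, up to 4 members of highest mean CPM in each list, the 5 largest log2 ratios per direction among genes of 100 CPM or more that passed the test between libraries, and the members of the neighbouring pairs. No gene of 100 CPM or more passed that test. Other genes are named with the statement that they were chosen after their values were seen. The lists cover smooth muscle, striated muscle, mesenchyme, epithelium, squamous epithelium, gastrointestinal epithelium, endocrine cells, the Mir183 cluster, pancreatic acinar cells, liver, neural cells, endothelium, erythroid cells, leukocytes, ciliated cells, pluripotent cells, let-7, the Mir17 clusters, the Hox clusters, the Dlk1-Dio3 cluster, the Igf2-H19 locus, the Sfmbt2 cluster and its relatives, the Mir15-Mir16 clusters and the Mir23-Mir27-Mir24 clusters.

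The test between libraries was tested on simulated counts drawn with counting noise alone from the means and totals of the real libraries. In it 353 genes were tested for replicate 2 over replicate 1. All 89 tested genes given a 4-fold change passed both thresholds. Of 100 genes given a 1.5-fold change, 81.0% passed the adjusted p alone and 1.0% passed both thresholds. Of 164 genes left without a change, 4.27% passed the adjusted p alone. Chi-square over its degrees of freedom was 1.08 in a simulation with no difference over 361 genes. It was 75.8 in the real libraries, so the simulated rates hold for counting noise and not for the spread between these libraries.

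Alternatives were the other count columns, other count minimums and pseudocounts, scaling by edgeR's TMM factors, by DESeq2's size factors or to totals without the 5 most abundant genes, each replicate alone, lists without their most abundant member, other log2 thresholds and summed gene copies. All named genes are miRNA genes, so a total over miRNA genes alone was not run as a separate setting. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for the scaling factors.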

Results

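MicroRNA levels were measured in the whole stomach of mouse embryos at 14.5 days of development, when the organ holds an epithelium surrounded by mesenchyme and developing muscle. The group comprised 2 biological replicates. Gene counts totalled 5004548 in replicate 1 and 4679914 in replicate 2, out of 8755979 and 8251892 reads. All levels are counts per 1000000 gene counts (CPM), mean ± SD with n = 2, and all coordinates are on GRCm38 (mm10).

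Among the counted reads, the miRNA profile of the stomach was led by Mir143, at 152490.3 ± 12395 CPM, or 15.2% of all gene counts. Mir143 is known from smooth muscle and mesenchymal cells. Reads that map to several places, equal to 48.5% ± 0.23 of gene counts, belong to no gene. The ranking and the shares therefore leave them out, and miRNAs with several genomic copies may rank too low. Mir143 (ENSMUSG00000065445.2) lies on chromosome 18 at 61649196 to 61649258, minus strand, outside any same-strand host gene of the annotation. Mir99a followed at 77959 ± 3697 CPM, from an intron of its host transcript Mir99ahg on chromosome 16 (77598936 to 77599000). Mir335, in an intron of the imprinted gene Mest on chromosome 6 (30741299 to 30741396), reached 53849.8 ± 1002 CPM. Mir10a, which lies in the Hoxb cluster on chromosome 11 (96317165 to 96317274), reached 44729 ± 372 CPM. Mirlet7g, in an intron of Wdr82 on chromosome 9 (106178840 to 106178927), had 42617 ± 172 CPM.

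Mir26b, in an intron of Ctdsp1, was counted at 33878 ± 106 CPM, Mirlet7i at 27882 ± 1109 CPM, Mir23b at 26684 ± 3171 CPM and Mir130a at 25832 ± 642 CPM. Mir17, the leading member of the Mir17hg transcript, stood at 20880.1 ± 2469 CPM. Mir126a, an endothelial miRNA within Egfl7, had 20389 ± 1732 CPM, and Mir429, an epithelial miRNA of the Mir200 family, had 19907 ± 932 CPM. Below these were Mir99b in an intron of Spaca6 (18253 ± 518 CPM), Mir30e in an intron of Nfyc (18109 ± 2864 CPM), the X-linked Mir322 (16594 ± 957 CPM) and Mir23a (16056 ± 356 CPM). Mir214 in the Dnm3os transcript (14616 ± 821 CPM), Mir21a in Vmp1 (13564 ± 64.8 CPM), Mir200c (11821 ± 905 CPM) and Mirlet7d (11263 ± 194 CPM) completed the 20 most abundant genes. The precursors of Mir23a and Mir23b share 20 nt or more, so their levels are uncertain. The other 18 genes of this group share no such stretch.

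**Figure D1:**
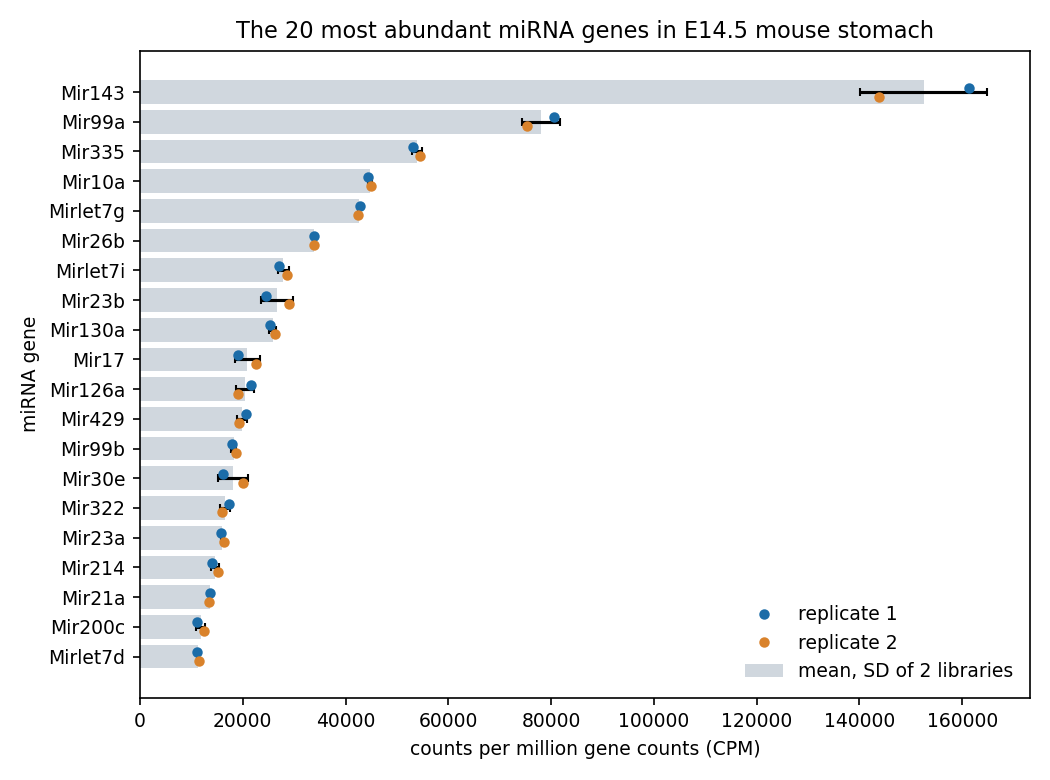
Mean CPM of the 20 most abundant miRNA genes in the embryonic stomach, as bars with the SD of 2 libraries, and the value of each library as a point. Mir143 stands at 152490.3 CPM and the lowest of the 20, Mirlet7d, at 11263 CPM.

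Counts were concentrated in few genes. The 10 most abundant genes held 50.7% ± 0.76 of gene counts (SD, n = 2) and the 20 most abundant held 66.7%. Of the 1973 genes counted, 361 were detected, and these held 99.98% of the gene counts in replicate 1 and 99.97% in replicate 2. At least 1 count was found for 665 genes in replicate 1 and for 662 in replicate 2, and 1251 genes had 0 counts in both. A count of 0 allows a level of up to 0.599 CPM in replicate 1 and 0.641 CPM in replicate 2. With a minimum of 1 count in both libraries, 605 genes were detected. With the own-strand column in place of both strands, 351 were detected.

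Among cell type markers, the smooth muscle list had the highest total, 155329 ± 12469 CPM, nearly all of it from Mir143. Mir145a, which neighbours Mir143 on chromosome 18 (61647825 to 61647894) and is also known from smooth muscle, contributed 2839 ± 73.5 CPM. Without Mir143 the list total was 2839 CPM. Mir143 exceeded Mir145a 55.8-fold in replicate 1 and 51.6-fold in replicate 2. Mir145b had 0 counts in both libraries.

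The epithelial list, made up of the Mir200 family, totalled 41460.4 ± 30.7 CPM with all 5 members detected. Mir429 and Mir200c led it, Mir200b followed at 7037 ± 45.4 CPM, and Mir141 had 1586 ± 18.7 CPM. The squamous epithelial list, of miRNAs known from stratified epithelia such as that of the mouse forestomach, totalled 16628 ± 0.13 CPM. Its members were Mir205 at 9768 ± 663 CPM and Mir203 at 6859.9 ± 663 CPM, and the very small SD of the total arose because Mir205 was higher in replicate 2 and Mir203 higher in replicate 1 by nearly the same amount. The gastrointestinal epithelial list, of miRNAs known from intestine, was lower, at 1434 ± 178 CPM. Mir192 had 801 ± 124 CPM, Mir194-2 398 ± 14.1 CPM, Mir215 200.2 ± 37.1 CPM and Mir194-1 34.9 ± 2.87 CPM. Mir194-1 and Mir194-2 share sequence, so this total leaves out reads that map to several places. The log2 ratio of the smooth muscle total over the epithelial total was 1.90 ± 0.12 (SD, n = 2), a 3.74-fold difference that was larger than the spread between replicates. An error common to both libraries would not show in that spread. The direction of the fold rests on Mir143. Without it, an alternative chosen after seeing the data, the log2 ratio was -3.87 ± 0.04, with the epithelial total 14.6-fold higher.

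The mesenchymal list totalled 15247 ± 873 CPM, with Mir214 its main member. Mir199b had 482 ± 22.1 CPM, Mir199a-2 139 ± 27.5 CPM and Mir199a-1 8.82 ± 2.02 CPM, and these 3 share sequence. The endothelial list consisted of Mir126a. The endocrine list totalled 5680.1 ± 542 CPM, of which Mir375, a miRNA of endocrine cells and of gastric and other epithelia, made up 5115 ± 617 CPM. Mir7b had 454 ± 64.3 CPM, Mir7-1 92.7 ± 15.8 CPM and Mir7-2 18.8 ± 4.80 CPM, and Mir7-1 and Mir7-2 share sequence. The Mir183 cluster, known from sensory and epithelial cells, totalled 8242 ± 1082 CPM, with Mir182 at 4414 ± 916 CPM, Mir183 at 2632 ± 41.4 CPM and Mir96 at 1196 ± 124 CPM.

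Markers of neural cells and striated muscle had lower totals than the smooth muscle and epithelial lists. The neural list totalled 2099 ± 165 CPM, of which Mir137 held 1750.4 ± 115 CPM, Mir128-1 107 ± 19.7 CPM, Mir138-1 91.6 ± 13.1 CPM and Mir138-2 77.9 ± 14.9 CPM. The smooth muscle total was 74.0-fold higher, a log2 ratio of 6.21 ± 0.23, and 1.35-fold higher without Mir143, a log2 ratio of 0.44 ± 0.15. Of the 14 neural genes counted, 13 share sequence, and among them Mir124a-1, Mir124a-2 and Mir9-2 had 0 counts in both libraries, and this total leaves out the reads that map to several places and Mir9-1, which is not among the genes counted. The striated muscle list totalled 111 ± 10.5 CPM, mostly from Mir208b, a miRNA of a myosin gene, at 90.7 ± 6.21 CPM. Mir206 had 12.8 ± 4.21 CPM, Mir1b 2.60 ± 0.85 CPM and Mir208a 2.17 ± 0.043 CPM. Mir133a-1 and Mir133a-2, which are abundant in heart and skeletal muscle and share sequence, had 0 counts in both libraries. The log2 ratio of the smooth muscle total over the striated muscle total was 10.45 ± 0.02, and 4.68 ± 0.10 without Mir143. The striated muscle total leaves out reads that map to several places and Mir1a-2, a list member not among the genes counted. Mir1a-1, Mir133a-1, Mir133a-2 and Mir133b, which share sequence, had at most 6 counts in either library, so the SD covers the spread of the counted reads alone.

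Blood markers were low. The erythroid list totalled 185 ± 47.6 CPM, with Mir451a at 158 ± 51.0 CPM, Mir144 at 22.0 ± 4.51 CPM and Mir486 at 4.36 ± 1.08 CPM, and the smooth muscle total exceeded it by a log2 ratio of 9.74 ± 0.49, or of 3.97 ± 0.41 without Mir143. The leukocyte list totalled 579 ± 27.0 CPM, with Mir223 of myeloid cells at 494 ± 15.5 CPM, Mir155 at 73.5 ± 13.0 CPM and Mir150 at 11.7 ± 1.49 CPM. Mir142, a miRNA of blood cells in the same list, is not among the genes counted, and neither is Mir486b of the erythroid list. With the opposite-strand counts of the gene that overlaps Mir142, an alternative chosen after seeing the data, the leukocyte total was 1051 CPM. The ciliated cell list totalled 476 ± 26.9 CPM, with Mir34c at 399.8 ± 28.2 CPM, Mir449a at 56.6 ± 3.89 CPM and Mir34b at 18.96 ± 2.80 CPM. The pluripotent cell list totalled 136 ± 1.04 CPM, with Mir302a at 48.4 ± 6.53 CPM, Mir302d at 44.2 ± 3.01 CPM and Mir302b at 27.1 ± 3.54 CPM. Mir302a and Mir302b share sequence, and Mir290b and Mir292b of this list are not among the genes counted. Of neighbouring organs, the liver miRNA Mir122 was counted at 61.3 ± 6.41 CPM. The pancreatic acinar list totalled 6.29 ± 0.43 CPM, with Mir217 at 4.22 ± 0.53 CPM the sole detected member of 3.

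**Figure D2:**
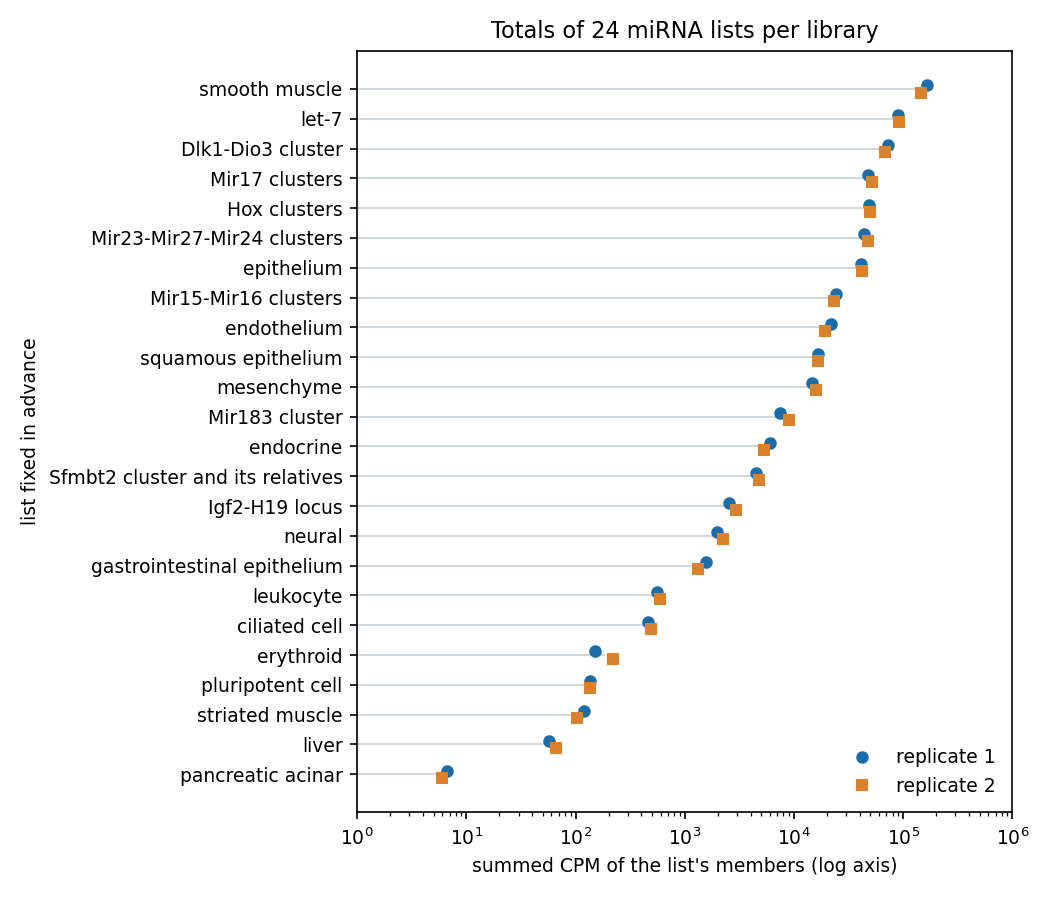
Summed CPM of 24 miRNA lists fixed in advance, on a log axis, with replicate 1 as circles and replicate 2 as squares. The smooth muscle list lies highest at a mean of 155329 CPM and the pancreatic acinar list lowest at 6.29 CPM.

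Among families and clusters, let-7, known for its rise during differentiation, totalled 90773 ± 1313 CPM over 10 detected genes. Mirlet7g and Mirlet7i made up most of it, and Mir98 had 5148 ± 45.0 CPM. Of these 10 genes, 5 share sequence, and the total leaves out the reads that map to several places. It also leaves out Mirlet7e and Mirlet7f-1, list members not among the genes counted. With the opposite-strand counts of the genes that overlap them, an alternative chosen after seeing the data, the total was 96004 CPM. The Mir17 clusters, known to promote proliferation, totalled 49712 ± 3361 CPM with all 15 members detected, among them Mir20a at 7992 ± 784 CPM, Mir93 at 6859.9 ± 418 CPM and Mir106b at 6419 ± 434 CPM. The miRNAs of the Hox clusters totalled 49328 ± 611 CPM, of which Mir10a was the main part, Mir10b had 3300.2 ± 213 CPM, Mir615 1256 ± 17.6 CPM and Mir196b 42.2 ± 7.70 CPM. The Mir23-Mir27-Mir24 clusters totalled 45552 ± 3229 CPM, with Mir27b at 2263 ± 228 CPM and Mir27a at 361 ± 57.5 CPM, and all 5 genes counted share sequence. Mir24-1 of this list is not among the genes counted. The Mir15-Mir16 clusters totalled 23832 ± 729 CPM, with Mir322 first, Mir15a at 2065 ± 148 CPM, Mir16-1 at 1622 ± 94.4 CPM and Mir15b at 1513 ± 1.60 CPM. Mir16-1 shares sequence, and Mir497 of this list is not among the genes counted. With the opposite-strand counts of the gene that overlaps Mir497, an alternative chosen after seeing the data, the total was 24513 CPM.

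The imprinted Dlk1-Dio3 cluster on chromosome 12, whose miRNAs are expressed from the maternal chromosome, totalled 70191 ± 3092 CPM. Of 54 genes fixed for it, 48 were counted, and of these 45 were detected and 34 reached 100 CPM or more. The total and the 34 include Mir299b, named after its values were seen, at 2057 CPM over both strands. Its own strand held 12 counts in replicate 1 and 11 in replicate 2, against 10640 and 9277 on the opposite strand. Mir127 (109592846 to 109592915) had 9404 ± 223 CPM, Mir411 8999 ± 573 CPM, Mir487b 7968 ± 49.5 CPM and Mir379 5922 ± 749.9 CPM. Mir411 and Mir487b share sequence. The Sfmbt2 cluster and its relatives, some of which lie on other chromosomes, totalled 4621 ± 176 CPM, with 10 of 69 genes detected. Mir467e had 1425 ± 19.2 CPM, Mir467d 1256 ± 44.2 CPM, Mir467c 903 ± 15.8 CPM and Mir669o 416 ± 61.0 CPM, and 67 of the 69 share sequence. In the Igf2-H19 locus, which totalled 2724 ± 269.6 CPM, Mir483 of Igf2 had 2571 ± 268 CPM and Mir675 of H19 had 153 ± 1.11 CPM.

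The libraries were then compared with each other to ask how far the profile of the stomach differed between replicates. Across the 361 detected genes, Pearson's r was 0.996 and Spearman's rho 0.994. Among the 196 genes of 100 CPM or more, the log2 ratio of replicate 2 over replicate 1 ran from -0.39 for Mir496a to 0.74 for Mir181b-2, both named after their values were seen, with an SD of 0.20. Mir181b-2 shares sequence. None of the 196 passed both thresholds of the exact binomial test, and the 20 most abundant genes lay between -0.17 and 0.32. Over all detected genes the chi-square was 75.8 per degree of freedom (360 degrees of freedom). This value and the counts of genes by adjusted p set the spread between libraries of separate biological replicates against counting noise alone, and describe these libraries. By adjusted p alone, 152 genes (42.1%) differed, 89 higher in replicate 2 and 63 higher in replicate 1. That split depended on the scaling. With edgeR's TMM factors it was 74 higher in replicate 2 against 94 higher in replicate 1, with DESeq2's size factors 58 against 115, and with totals without the 5 most abundant genes 74 against 92.

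Past both thresholds, 4 genes differed, and all were higher in replicate 1 and below 100 CPM. They are named here because the count is small and were chosen after their values were seen. Mir802, on chromosome 16 at 93369720 to 93369816 and known from liver, pancreas and intestine, had 226 counts in replicate 1 and 12 in replicate 2. Its log2 ratio was -4.14 (95% interval -5.11 to -3.31, adjusted p = 3.36e-48 by the exact binomial test with Benjamini-Hochberg adjustment). Gm26117 had 54 and 10 counts and a log2 ratio of -2.34. Mir6240 had 56 and 23 counts and a log2 ratio of -1.19. Mir450-2, which shares sequence, had 105 and 48 counts and a log2 ratio of -1.03. With the counts of gene copies summed before the test, 3 of these genes passed and Mir450-2 did not.

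**Figure D3:**
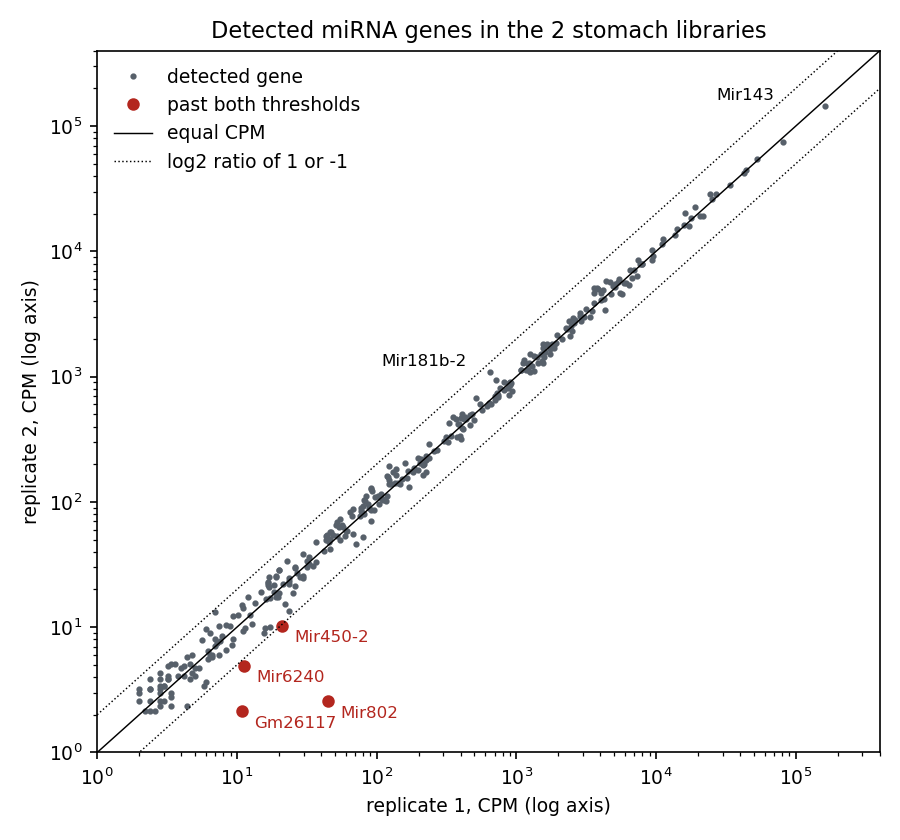
CPM of each of the 361 detected miRNA genes in replicate 1 and in replicate 2, both on log axes, with lines of equal CPM and of a log2 ratio of 1 and -1. The 4 genes past both thresholds of the exact binomial test are in red, and Mir802 lies farthest from equality with 226 counts in replicate 1 and 12 in replicate 2.

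Of the 18 lists with 3 or more detected members, the Dlk1-Dio3 cluster lay lowest against random lists matched on expression. Its median log2 ratio was -0.08, at the 0.015th percentile, with 31 of 45 members below 0 and 14 above. The gastrointestinal epithelial list had a median of -0.24, at the 0.345th percentile, with all 4 members below 0, and the Mir23-Mir27-Mir24 clusters a median of -0.14, at percentile 2.42. At the other end, the erythroid list had a median of 0.51, at the 97.6th percentile, with Mir451a at a log2 ratio of 0.67 and Mir144 at -0.42. Its median is the ratio of Mir486, with 18 and 24 counts, and was 0.32 with the own-strand column. The neural list had a median of 0.29, at the 95.8th percentile. The mesenchymal list (94.8th percentile), let-7 (94.4th) and the Mir183 cluster (92.6th) also had medians above 0, of 0.26, 0.10 and 0.21. Scaling by TMM factors or size factors shifted every log2 ratio by the same amount, -0.05 or -0.09, and so left the percentiles as they were. The medians then became -0.13 and -0.17 for the Dlk1-Dio3 cluster and 0.05 and 0.01 for let-7, and with size factors -0.23 for the Mir23-Mir27-Mir24 clusters, 0.17 for the mesenchymal list and 0.12 for the Mir183 cluster. Without members that share sequence, an alternative chosen after seeing the data, the medians were 0.13 for the neural list (Mir137 and no other detected member), 0.11 for the mesenchymal list (Mir214 alone) and 0.02 for let-7, and the Mir23-Mir27-Mir24 clusters had no member left. None of these shifts reached a log2 ratio of 1, and each rests on the same 2 libraries. The random lists were drawn gene by gene. The Dlk1-Dio3 members lie in 1 cluster, and Mir192 and Mir194-2 are neighbours, as are Mir215 and Mir194-1. Neighbouring members may shift together, which the percentiles do not allow for.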

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

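The tests on the opposite-strand counts were chosen after the values were seen. The separate strand columns showed genes whose counts came from the strand opposite to their annotation, above the limit that a count of 0 allows, and the main comparisons use the both-strand column, the strand columns entering alternatives alone. For 10 genes the opposite strand held more counts than their own strand in both libraries, with 24 counts on the own strand in all. Mean opposite-strand levels were 5865 CPM for Gm25301, 5694 CPM for Gm24321, 5139.6 CPM for Gm25927, 3191 CPM for Gm25252 and 2724 CPM for Gm24083. They were 2054 CPM for Mir299b, 1430.4 CPM for Gm25750, 682 CPM for Mir497b, 472 CPM for Mir142b and 92.1 CPM for Gm24111. These genes were named because of these values.

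All 10 genes (100%) overlap, on the opposite strand, a miRNA gene of GENCODE M21 that is not among the genes counted: Mir378a, Mir409, Mirlet7e, Mir376a, Mir191, Mir299a, Mir380, Mir497, Mir142 and Mirlet7f-1, in the order of the levels above. Of the 351 other detected genes, 15 (4.27%) overlap such a gene. A general loss of strand information is argued against, since opposite-strand counts made up 0.00847% of the counts of all other genes. For the 10 genes, the own strand held 24 counts against 264833 on the opposite strand. Their both-strand levels therefore do not measure their own strand. A candidate explanation that stays open is that the opposite-strand counts are reads of the overlapping miRNA, which would make the both-strand levels of the 10 genes those of their partners. No biological explanation was tested, since the design has 1 group.

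Reads that map to several places, which the comparisons do not use, made up 27.6% of all reads, with 2437052 in replicate 1 and 2263676 in replicate 2.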

How the results depend on the processing

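Adding opposite-strand counts of genes not counted, leaving out members that share sequence and leaving Mir143 out of the folds were chosen after seeing the data. The number of detected genes was 351 with the own-strand column, 14 with the opposite-strand column and 605 with a minimum of 1 count. The 10 most abundant genes held 52.1% of the own-strand column and 99.7% of the opposite-strand column, and with each replicate alone from 50.1% to 51.5%. The number of genes that differed between the libraries was 1 with the opposite-strand column, 0 with a minimum of 100 counts, 152 with no minimum log2 ratio and 2 with a log2 ratio of 2 or more. The gene of the opposite-strand column was Mir337, named after its value was seen, which is not among the 4 of the main setting. The opposite-strand column holds 2.74% of gene counts and the count minimums and ratios change which genes can pass, so these moves follow from how the settings are built. With either scaling alternative of edgeR or DESeq2, all 4 genes remained past both thresholds, and with copies summed 3 did, without Mir450-2. Chi-square per degree of freedom, 75.8, was 38.7 with 1 count over both libraries and 48.4 with the opposite-strand column. It was higher with TMM factors (84.7), with size factors (102.1) and with a minimum of 100 counts (103.9). Pearson's r lay between 0.995 and 0.998 in all alternatives. That is within its bootstrap interval over genes, 0.992 to 0.998, which does not measure the spread between libraries. The log2 folds of smooth muscle stayed within their SD with the own-strand column, but without Mir143 became -3.87 over epithelium, 4.68 over striated muscle, 0.44 over neural and 3.97 over erythroid, since Mir143 makes up most of the list. No smooth muscle or epithelial counts lie on the opposite strand, so that column gave no fold between lists.

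With each replicate alone, the 24 list totals and the folds moved by less than 1 SD, which n = 2 ensures by construction and which shows no stability. Scaling by TMM or size factors moved 1 of 24 totals, squamous epithelium, by more than its SD. Opposite-strand counts of genes not counted brought leukocytes to 1051, let-7 to 96004 and the Dlk1-Dio3 cluster to 80506 CPM. Totals without the 5 most abundant genes raised all 24. Without their most abundant member, all 22 lists that have another fell by more than their SD. The median ratios of the epithelial and endocrine lists, 0.01 and 0.02, changed sign with TMM, size factors and totals without the 5 most abundant genes, and those of the leukocyte, Hox and Sfmbt2 lists with size factors. These scalings shift every log2 ratio by a constant, so the changes of sign follow by construction from medians near 0. Those of the squamous and endothelial lists changed sign with the opposite-strand column, the cause not being tested. Depth limits genes near 10 counts, which is 2.00 CPM or 2.14 CPM. No paired analysis was possible because there is 1 group.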

Other observations

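All tests in this part except the sign test over neighbouring pairs were chosen after the result was seen. Some neighbouring precursors of the same strand were counted at very different levels. Detected genes that share sequence were left out first. Over the 72 pairs of genes then next to each other, with starts under 10 kb apart, the median ratio of the higher to the lower member, which is above 1 by construction, was 6.46. Of these pairs 38 lie in the Dlk1-Dio3 region, and over the other 34 the median ratio was 5.25. In the Mir200 family, Mir429 exceeded Mir200a by a log2 fold of 4.16 ± 0.11 (SD, n = 2) and Mir200c exceeded Mir141 by 2.90 ± 0.13. Mir322 exceeded Mir503 by 4.23 ± 0.04, and Mir20a exceeded Mir19a of the same transcript by 7.37 ± 0.06. By contrast Mir93 and Mir106b differed by 0.10 ± 0.19, less than the spread between replicates.

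Precursors whose mature sequence has several genomic copies were compared with a partner of the same transcript, in 19 pairs fixed in advance. The partner is not always the next precursor, as Mir19b-1 lies between Mir20a and Mir92-1. The multi-copy member was lower in 17 of 17 measured pairs (exact two-sided sign test, p = 1.53e-05). The difference ran from 1.27-fold for Mir16-1 under Mir15a to 310.2-fold for Mir30c-1 under Mir30e, with a median of 6.65-fold. The partners Mir27a and Mir29c themselves share sequence, and without these pairs, an alternative chosen after seeing the data, it was 15 of 15 (exact two-sided sign test, p = 6.1e-05). The test takes the pairs as independent, but several hold copies of the same mature sequence, such as Mir30c-1 and Mir30c-2. Reads that map to several places were not counted for any gene, and a candidate explanation is that this lowered the multi-copy members. Since that rule can remove counts of the multi-copy members, the sign test was tilted towards this direction in advance. It therefore does not show that the true levels of these members are lower. The missing counts were taken as those each multi-copy member would need to equal its partner. They would be 30.0% of the reads that map to several places in the library with the higher share. Such equality is not given, since neighbours that share no sequence differed by a median of 6.46-fold, so this share decides nothing. Outside the pairs, genes numbered under 500 that share sequence had a median log2(CPM + 1) lower by a difference of -7.03 (125 against 190 genes, permutation p = 1e-05, the smallest that 100000 permutations give), or of -4.53 (78 against 189 genes, permutation p = 1e-05) without the Sfmbt2 list, which holds 47 of the 125 and whose copies are not independent. The size of the folds does not separate the explanation from ordinary differences in processing or stability, since 34 of the 72 pairs that share no sequence (47.2%), and 15 of the 34 outside the Dlk1-Dio3 region, differed by more than the 6.65-fold median, and no biological explanation was tested.

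Mir802 had 226 counts in replicate 1 and 12 in replicate 2, the most extreme ratio among 361 detected genes. Liver tissue carried along in replicate 1 is argued against by Mir122, whose log2 ratio of replicate 2 over replicate 1 was 0.21 with a lower 95% bound of -0.0235. That bound covers counting error only. Pancreas carried along was not tested and stays open. The pancreatic acinar list had 6.59 CPM in replicate 1 and 5.98 CPM in replicate 2, with Mir217, its sole detected member, at 23 and 18 counts. Gut epithelium from outside the stomach in replicate 1 stays open as a hypothesis. The gastrointestinal epithelial list lay at the 0.345th percentile, with Mir192 at 889 and 713 CPM and Mir215 at 226 and 174 CPM, but 3 of the 18 lists lay below the 2.5th percentile, 2 of them unrelated to gut, and all 4 members were detected in both libraries. A difference between the embryos or the collection days stays open as well and was not tested.

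With no filter beyond 1 count over both libraries, 6 genes passed both thresholds. The added ones were Mir6538 and Mir669f, named after their values were seen, and Mir669f had 5 counts in replicate 1 and 176 in replicate 2.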
